A study of Mus musculus with 213 samples.

How the data were processed

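Single CD4 T cells of spleen, colon lamina propria, visceral adipose tissue and injured muscle were measured by CEL-seq, with 213 samples of 1 cell each. Per the labels' protocols, spleen was dissociated mechanically, the other tissues were digested with enzymes, and live TCRb+ CD4+ cells were sorted singly with their fluorescence recorded. Per the submitters' processing notes, reads were aligned to the mm10 genome with TopHat2 and handled with SAMtools; no versions were given. The authors deposited 1 table of 24175 genes by 213 cells, whose name speaks of counts. Every value in it was 0, 1 or 2, and 53.0% of detections stood at 2. All 213 column sums equalled the molecular identifier totals given in the labels. The deposited values were therefore read as a score of 0, 1 or 2 per gene and cell and not as counts; no note states how the authors limited them. The plan written before the data were examined had assumed counts. Detection (level 1 or 2) replaced the count in the shares of cells and the list ratios. For the list ratios, the sum of levels as deposited was kept as an alternative. The sizes used to name genes, and the list medians taken from them, used summed levels as deposited. The table held no mitochondrial or spike-in genes.

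All 213 columns were matched to their samples by title. Cells with a summed level below 500 were left out, which kept 183 cells. Groups followed the labels' tissue and day, each a single sample of cells, since the labels named no animals. Spleen cells were split by the reporter fluorescence in the labels, at least 10000 against less than 2000, and muscle day 1 cells at 10000. Mapped reads per unit of summed level ran from 5.59 to 461, with a median of 39.6.

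There were 7 comparisons: reporter-high against reporter-low spleen cells, the equal-weight mean of the 4 non-lymphoid groups against reporter-high spleen cells, each of colon, VAT and muscle against the equal-weight mean of the other tissues (muscle being the mean of its 2 days), day 4 against day 1 in muscle, and the reporter ranges in muscle at day 1. With 1 sample per group, no test was run and no p-value is given. The share of cells with a transcript has an exact Clopper-Pearson 95% interval. A count of 0 is given with the share that 3 cells would make. Gene lists are given as their share of all detections and as the log2 ratio of that share. The interval of the ratio is exact and conditional for comparisons of 1 set of cells with another, and simulated from Poisson counts for means of groups. All intervals and floors cover counting error only, not differences between animals, libraries or cells.

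The 26 lists, holding 380 genes of which 376 were in the table under their symbol or an older one, were fixed in advance. The 16 lists of T cell programs were regulatory T cell core, naive and resting, non-lymphoid regulatory T cell, VAT regulatory T cell, muscle regulatory T cell, colon regulatory T cell, helper effector, cell cycle, interferon response, immediate early and stress, NF-kB and TNF receptor family, glycolysis, oxidative phosphorylation, migration and adhesion, MHC class I, and pan-T cell. The 10 marker lists were B cell, macrophage with monocyte and dendritic cell, neutrophil, CD8 T and NK cell, muscle fibre, fibroblast, adipocyte, endothelial, colon epithelium, and red cell. Some genes belong to several lists, such as Il10, Il1rl1 and Itgae. The median size over the members of a list was placed among 10000 random lists of the same length matched on mean expression, as a description of these cells.

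Genes were named by a fixed rule. The size of a difference was the log2 ratio of summed levels as CPM with 100 added to each side. In each direction the 12 genes of largest size, of at least 1, were named among those with at least 10 summed units and 20% of cells on the higher side, with no more than 33.3% of the units in 1 cell. Every library pool with at least 4 cells of the higher side had to lie above the lower side, the 4 non-lymphoid groups had to share the direction, and a tissue had to lie beyond each other group. Ribosomal protein genes, genes named Gm with digits or ending in Rik, and rows that name no gene were left out of naming. Foxp3 and members of the lists were named besides, as examples of their list.

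Cells differed in depth, so shares and ratios were also computed with each cell of at least 1000 units thinned to 1000, as the expected detection under random draws without replacement. Because levels stop at 2, thinning lowers the share of abundant genes more in deep cells than it would with full counts. Other alternatives were equal weight per cell, a minimum of 1000 units, no ribosomal protein genes, each barcode set alone, each library pool left out, the reporter ranges within each library pool, other reporter limits, other sums of the groups, pseudocounts of 10 and 300, and no minimum of 10 units. In the umi set, muscle day 4 held 2 cells and kept its full weight in means of groups. Protein and transcript were compared by splitting cells of a group at the median fluorescence. Gene positions came from GENCODE release M21 on GRCm38, the build that mm10 names.

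The scripts were tested on simulated data in which 200 of 16005 genes were changed 4-fold. For the comparison of the spleen reporter ranges, 90% of changed genes had the right direction and the median size was 1.44 for those made higher and -0.66 for those made lower, so most genes 4-fold lower would not reach the minimum size for naming. Unchanged lists of 20 genes had 0 in their interval in 98.3% of 300 draws. For muscle day 4 against day 1, 98% of changed genes had the right direction. Of unchanged genes with at least 10 summed units, 0.748% reached a size of 1. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.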

Results

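Single CD4 T cells (TCRb+ CD4+ DAPI-) of male mice were profiled by CEL-seq, a method that tags the transcripts of each sorted cell with a cell barcode and a molecular identifier. Each of the 213 samples was 1 cell, sorted with its fluorescence recorded, and the labels named no animals. The groups were spleen (41 cells), colon lamina propria (colon LP, 16 cells), visceral adipose tissue (VAT, 22 cells), and injured muscle taken 1 day (85 cells) or 4 days (49 cells) after cardiotoxin, a snake toxin that kills muscle fibres. Spleen and muscle cells carried a green reporter of Foxp3, the transcription factor that defines regulatory T cells. Colon cells carried a Thy1.1 reporter of the same gene, and VAT cells were stained for CD25, ST2 and Klrg1 with no reporter value recorded. Because cells could not be assigned to animals, each group was taken as 1 sample and no test was made, and the intervals below are 95% intervals for counting error only.

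The deposited table held a level of 0, 1 or 2 for 24175 genes in each cell, and a gene was counted as detected at level 1 or 2. The 183 cells with a summed level of at least 500 were kept, and their summed levels ran from 568 to 4687. The median number of genes detected per cell was 945 in spleen, 1507.5 in colon, 1561.5 in VAT, 1400 in muscle at day 1 and 1855 in muscle at day 4. All 30 cells of 1 of the 2 day 4 library pools fell below the minimum, so day 4 rested on 19 cells of 1 pool. In spleen, 21 cells had reporter fluorescence of at least 10000 (reporter-high), 13 had less than 2000 (reporter-low), and 7 lay between and were left out of the comparison of the reporter ranges. These were ranges of a label value, since the sort gates were not given. Taken as 3 cells, a count of 0 allows a share of up to 14.3% in reporter-high spleen, 23.1% in reporter-low spleen, 18.8% in colon, 13.6% in VAT, 3.53% in muscle day 1 and 15.8% in muscle day 4 cells. The sample titles named 2 barcode sets, ls and umi, and spleen cells of the ls set were the shallowest, with a median of 589 genes in reporter-high cells against 1599 in the umi set.

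**Figure D1:**
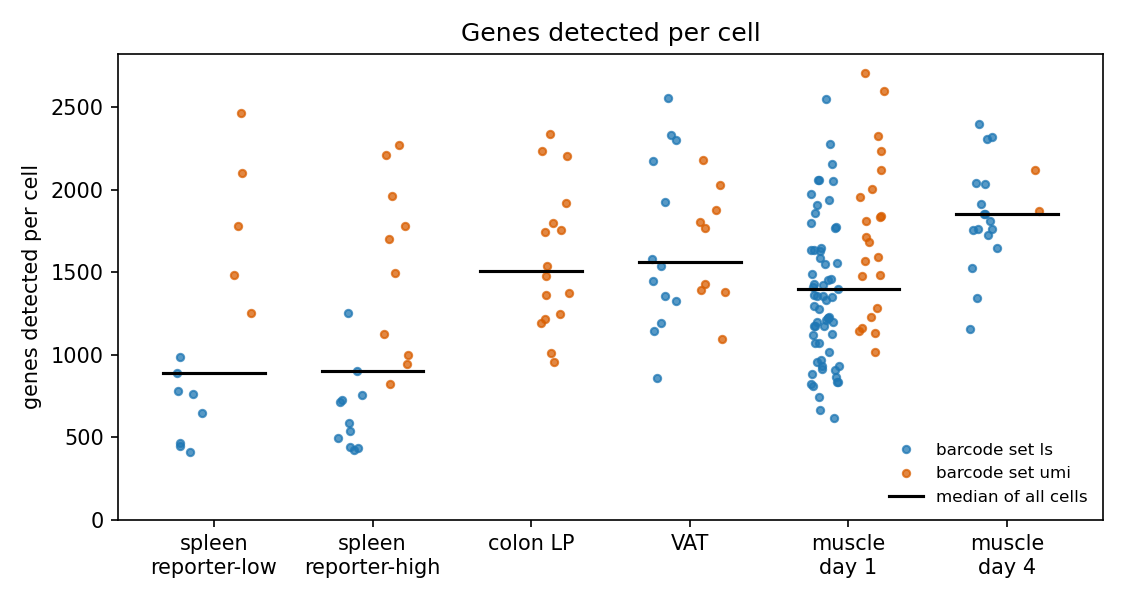
Genes detected per cell (y axis) for each group (x axis); each point is 1 cell, coloured by barcode set, and the line is the median of all cells of the group. Medians were 888 in spleen reporter-low, 899 in spleen reporter-high, 1507.5 in colon LP, 1561.5 in VAT, 1400 in muscle day 1 and 1855 in muscle day 4 cells.

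The first comparison asked how reporter-high spleen CD4 T cells, the range holding Foxp3-expressing regulatory cells, differed from reporter-low conventional cells. Reporter-high cells had more transcripts of regulatory T cell genes taken as a list, among them the tumour necrosis factor (TNF) receptor family genes Tnfrsf18 and Tnfrsf4, though not Tnfrsf9. Tnfrsf18, which encodes GITR, and Folr4, an older symbol of Izumo1r that encodes a folate receptor of regulatory T cells, were each found in 8 of 21 reporter-high cells (38.1%, interval 18.1 to 61.6) and in 0 of 13 reporter-low cells, which allows a share of up to 23.1%. The pan-T cell list was higher in reporter-high cells too, so the difference in regulatory genes could not be told apart from it. Reporter-low cells had more transcripts of the cell cycle list, and more of red cells. Neither range had a Foxp3 transcript: it was found in 0 of 21 and 0 of 13 cells, which allows shares of up to 14.3% and 23.1%.

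The regulatory T cell core list (20 genes, among them Foxp3, Il2ra, Ctla4 and Ikzf2) made up 4.56 per 1000 detections in reporter-high and 2.49 in reporter-low spleen cells, a log2 ratio of 0.87 (0.31 to 1.46). The ratio was 1.20 with each cell thinned to 1000 units. Thinning left out shallower cells and kept 15 reporter-high and 9 reporter-low cells, so this value mixes depth with a change of cells. Within the 3 library pools, which each held both ranges, the ratio was 1.43 (0.21 to 2.94), 0.58 (-0.32 to 1.51) and 0.86 (-0.20 to 2.0). The median of the 10 list members measured lay at percentile 99.7 of random lists matched on mean expression. Tnfrsf4, which encodes OX40, was found in 33.3% of reporter-high and 7.69% of reporter-low cells, and Batf, a transcription factor of effector regulatory cells, in 47.6% and 7.69%. Tnfrsf9, with too few units to be measured, went the other way, in 14.3% and 30.8%. Ctla4 (42.9% and 38.5%) and Ikzf2 (42.9% and 30.8%) differed by less than their intervals. The list of NF-kB and TNF receptor family genes had a log2 ratio of 1.32 (0.53 to 2.18), the migration and adhesion list 0.64 (0.11 to 1.21) and the pan-T cell list 0.73 (0.17 to 1.31). In the last of these, Cd2, an adhesion receptor of T cells, was found in 13 of 21 reporter-high cells (61.9%, interval 38.4 to 81.9) and 1 of 13 reporter-low cells (7.69%, interval 0.195 to 36.0). The core list ratio lay within the interval of the pan-T cell ratio. More regulatory T cell transcripts could thus not be told apart from more T cell transcripts of any kind. The integrin subunits Itgal (52.4% against 7.69%) and Itgb7 (57.1% against 15.4%) were also higher in reporter-high cells. The cell cycle list was lower in reporter-high cells, with a log2 ratio of -0.90 (-1.42 to -0.39), and within the 3 pools it was -0.77, -1.31 and -1.36. Its tubulin members Tubb5 (38.1% of reporter-high and 61.5% of reporter-low cells) and Tuba1b (9.52% and 30.8%) went the same way, while Hmgb2, a chromatin protein, went the other way (38.1% and 7.69%). In the ls barcode set alone the cell cycle ratio was -0.50 (-1.39 to 0.39). The red cell list was also lower in reporter-high cells, with a log2 ratio of -0.85 (-1.56 to -0.13). Markers of other blood cells went both ways, with Cd79a in 9.52% of reporter-high and 30.8% of reporter-low cells, Cd79b in 19.0% and 7.69%, S100a9 in 42.9% and 30.8%, and Cst3 in 33.3% and 0 of 13, which allows up to 23.1%. The naive and resting list, with Lef1 in 14.3% of reporter-high and 46.2% of reporter-low cells and Klf2 in 28.6% and 69.2%, had a log2 ratio of -0.41 (-1.0 to 0.18), which was not separable from 0 at this depth. It was -1.15 (-2.22 to -0.13) in the ls barcode set alone and 0.02 (-0.74 to 0.81) in the deeper umi set, and within the 3 pools it was -1.18, 0.13 and -0.17.

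Among single genes, Spata13, an exchange factor for small GTPases, and Tsx, an X-linked gene, led those higher in reporter-high spleen cells, with 42.9% and 47.6% of cells. Folr4, Tnfrsf18, Prr13, Vps54, Gnb1, Lsm14a, Gna11, Gramd1a and Pacs2 were also higher in reporter-high cells, and like Spata13 and Tsx were found in 0 of 13 reporter-low cells. Micu1, a regulator of mitochondrial calcium uptake, Ranbp10 and Tmem70 were each found in 6 of 13 reporter-low cells (46.2%) and 0 of 21 reporter-high cells, which allows a share of up to 14.3%. Ddx3x, an RNA helicase, was found in 61.5% of reporter-low and 4.76% of reporter-high cells, and Tmpo, a protein of the inner nuclear membrane, in 69.2% and 9.52%. With 200 of 16005 genes changed 4-fold in simulated data for this comparison, 5.24% of unchanged genes reached the minimum size for naming a gene.

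The next comparison asked which transcripts set CD4 T cells of the non-lymphoid groups (colon LP, VAT and muscle at both days) apart from reporter-high spleen cells. Cd69 and Il2ra, both induced by activation, were found in a larger share of cells in each non-lymphoid group, although for colon the intervals overlapped those of spleen. Cd69, whose product holds T cells in tissues, was found in 0 of 21 reporter-high spleen cells, which allows a share of up to 14.3%, and in 25% of colon, 59.1% of VAT, 51.8% of muscle day 1 and 52.6% of muscle day 4 cells. Il2ra, which encodes CD25, was found in 4.76% of reporter-high spleen cells (interval 0.120 to 23.8), 18.8% of colon cells (4.05 to 45.6), 72.7% of VAT cells (49.8 to 89.3), 60% of muscle day 1 cells (48.8 to 70.5) and 68.4% of muscle day 4 cells (43.4 to 87.4). The calcium-binding proteins S100a4 and S100a6 and the lectin Lgals1 were found in a larger share of VAT and muscle cells, while for colon their intervals overlapped those of reporter-high spleen, with S100a6 in 19.0% of reporter-high spleen, 56.2% of colon, 90.9% of VAT and 97.6% of muscle day 1 cells.

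The non-lymphoid regulatory T cell list (30 genes, among them Il1rl1, Areg, Klrg1, Gata3, Gzmb and S100a4) made up 9.52 per 1000 detections in the mean of the 4 non-lymphoid groups and 7.40 in reporter-high spleen cells, a log2 ratio of 0.36 (0.14 to 0.61). Thinned to 1000 units the ratio was 0.50, with 139 non-lymphoid and 15 reporter-high spleen cells deep enough to be kept. Within the umi barcode set alone it was 0.047 (-0.23 to 0.34, 49 against 10 cells), so the difference did not hold in that set. Only 2 of the 49 cells were muscle day 4 cells, a group that weighed the same as the others. Among cells with 1000 to 2000 genes detected it was 0.20 (-0.11 to 0.55; 98 against 6 cells). In reporter-high spleen the list made up 4.26 per 1000 detections in the shallow ls cells and 8.88 in the deeper umi cells, and depth and barcode set could not be separated there. After thinning, the list members Rora, Srgn and Cd44 were no longer higher in colon than in reporter-high spleen cells. This cannot show that depth made their difference, since levels have a ceiling. Thinning therefore lowers abundant genes more in the deeper colon cells by construction. The thinned share of S100a6 was 13.9% in reporter-high spleen, 30.5% in colon, 56.3% in VAT and 69.5% in muscle day 1 cells, and that of Il2ra 3.09%, 10.5%, 40.5% and 38.0%. The muscle regulatory T cell list had a log2 ratio of 0.56 (0.13 to 1.09), the glycolysis list 0.46 (0.03 to 1.01) and the immediate early and stress list 0.25 (0.03 to 0.49). In the umi barcode set alone these lists had ratios of 0.25, 0.19 and 0.08, each with 0 inside its interval. The naive and resting list had 0.05 (-0.33 to 0.50) and the regulatory T cell core list 0.11 (-0.17 to 0.43), neither separable from 0. Against all spleen cells, reporter-low ones included, the core list had 0.58 (0.34 to 0.83). The groups differed also in strain, age, stain, digestion and library pool, none of which could be told apart from tissue in this comparison or between the tissues. The same held for the reporter in colon and VAT, while spleen and muscle cells both carried a green reporter of Foxp3. Spleen cells were also chosen by reporter fluorescence here, while all kept cells of the other groups were used. Of 85 muscle day 1 cells, 43 lay below the spleen limit of 10000. The mix of brighter and dimmer cells could thus not be told apart from tissue.

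Further genes higher in the non-lymphoid groups were the kinase Rock1, which drives contraction during migration, and Chmp4b, Brd2 and Stx11, each found in 0 of 21 reporter-high spleen cells, with Ddx3x, P2ry10, Mif, Hmgcs1, Tmem107 and Cldn18. Transcripts higher in reporter-high spleen cells included those of other blood cells. The haemoglobin gene Hbb-bs was found in 47.6% of reporter-high spleen, 43.8% of colon and 0 of 22 VAT cells, which allows a share of up to 13.6%. It was found in 0 of 85 muscle day 1 cells, which allows up to 3.53%. S100a9, an abundant neutrophil protein, was found in 42.9% of reporter-high spleen and 1.18% of muscle day 1 cells. Marcksl1, a regulator of the actin cortex, was found in 57.1% of reporter-high spleen cells. Mageb16-ps1, Gng12, Larp4, Ttc14, Ddb2, Tcaim, Hbb-bt, Fam178a and Mettl21e completed the genes named as higher in spleen. Hba-a1, Hbb-bs and Hbb-bt have near-identical copies whose reads the counting could split, as do Hspa1b and Rnu2-10.

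**Figure D2:**
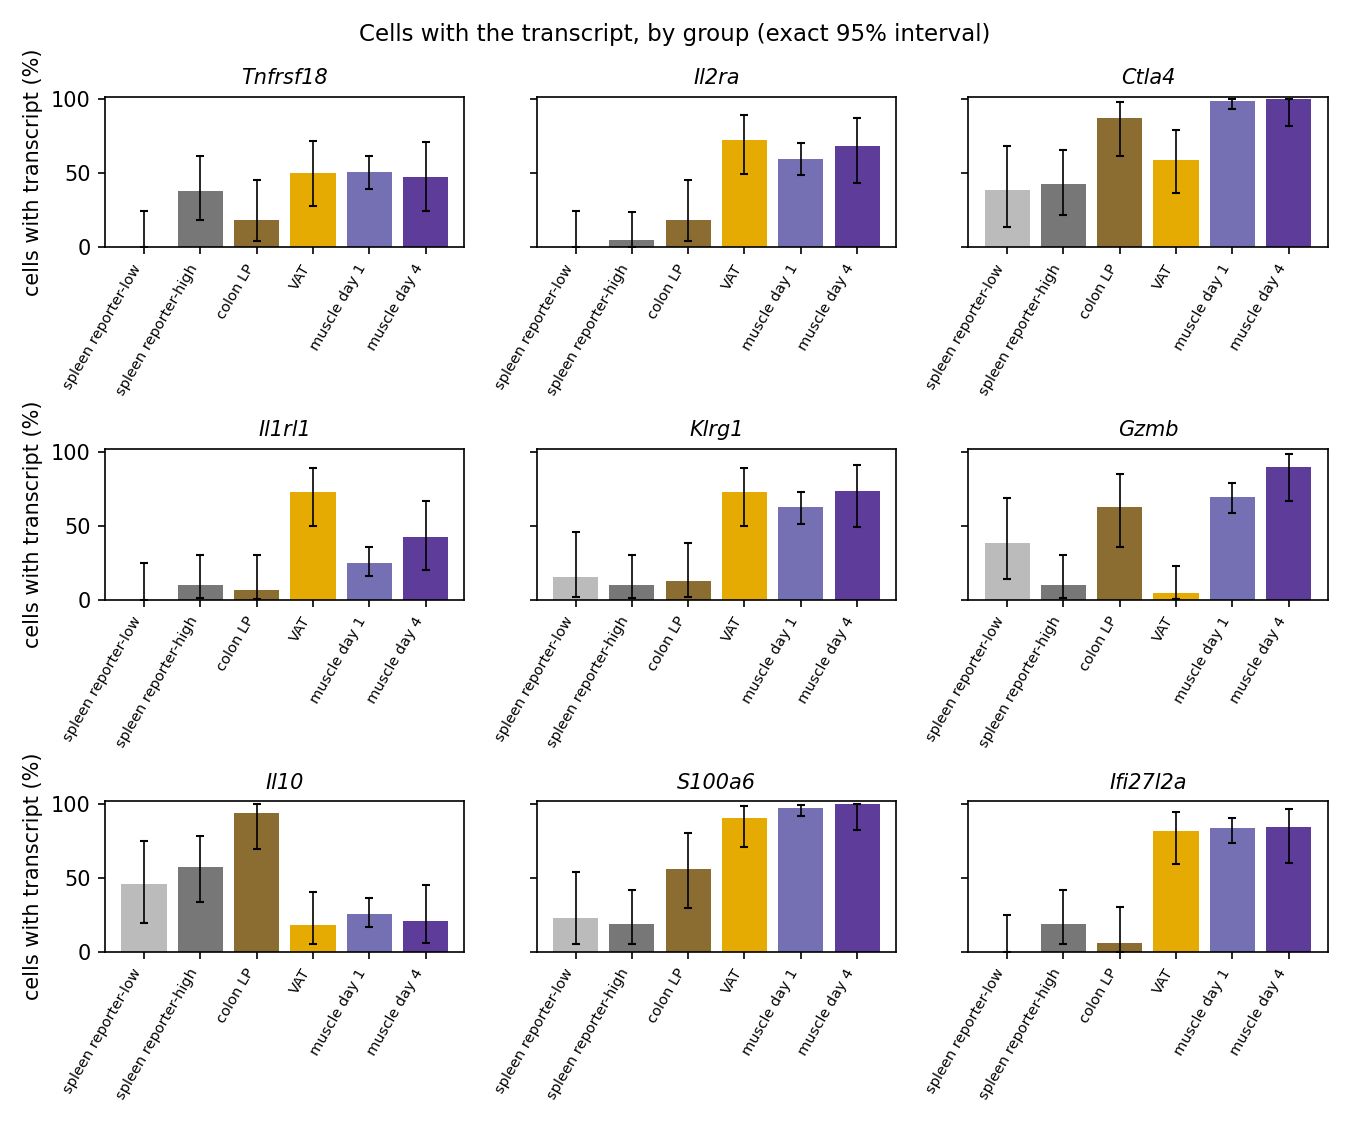
Percent of cells in which the transcript was detected (y axis) for 9 genes in the 6 sets of cells (x axis); bars are shares and whiskers exact 95% intervals for counting error. Il10 was found in 93.8% of colon and 18.2% of VAT cells, Gzmb in 4.55% of VAT and 89.5% of muscle day 4 cells, and Il1rl1 in 72.7% of VAT and 6.25% of colon cells.

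Colon lamina propria cells were compared with VAT and muscle cells to find transcripts distinct to the gut. Il10, the gene of an anti-inflammatory cytokine, was found in most colon cells and in few VAT or muscle cells. It was not distinct to the gut once spleen was included. Il10 was found in 57.1% of reporter-high and 46.2% of reporter-low spleen cells, which were not part of this comparison. Transcripts of NF-kB signalling and interferon response genes were scarcer in colon cells than in VAT or muscle cells. A low share of the NF-kB and TNF receptor family list was not distinct to the gut once spleen was included. Per 1000 detections it made up 1.74 in colon, and 1.30 in reporter-low spleen cells of the ls set and less in the umi set. In reporter-high spleen cells it made up 2.48 in the ls and 3.14 in the umi set. Il10 was detected in 15 of 16 colon cells (93.8%, interval 69.8 to 99.8), 4 of 22 VAT cells (18.2%, 5.19 to 40.3), 25.9% of muscle day 1 cells and 21.1% of muscle day 4 cells. Thinned to 1000 units, Il10 stood at 63.4% in colon and 13.0% in VAT cells.

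The colon regulatory T cell list (17 genes) had a log2 ratio of 0.25 (-0.10 to 0.56) against the other tissues, not separable from 0. Of its members, the gut-homing receptor Ccr9 was found in 37.5% of colon, 18.2% of VAT and 8.24% of muscle day 1 cells, and the ligand-activated factor Ahr in 31.2%, 13.6% and 10.6%. Rorc, which encodes the factor RORgt of gut regulatory cells, was found in 0 of 16 colon cells, which allows a share of up to 18.8%, in 0 of 22 VAT cells and in 10.6% of muscle day 1 cells. The NF-kB and TNF receptor family list was lower in colon, with a log2 ratio of -1.21 (-1.71 to -0.81) and -1.25 after thinning. Its member Nfkbia, the inhibitor that NF-kB itself induces, was found in 43.8% of colon, 100% of VAT and 92.9% of muscle day 1 cells, and Nfkb1 in 6.25%, 63.6% and 44.7%. The interferon response list had a log2 ratio of -0.96 (-1.46 to -0.56). Ifi27l2a, an interferon-induced gene, was found in 1 of 16 colon cells (6.25%, interval 0.158 to 30.2), 81.8% of VAT, 83.5% of muscle day 1 and 84.2% of muscle day 4 cells. It was also scarce in reporter-high spleen cells, with 19.0%. The regulatory T cell core list (-0.33, -0.65 to -0.05), the non-lymphoid regulatory T cell list (-0.26, -0.48 to -0.06), the immediate early and stress list (-0.39, -0.63 to -0.17) and the oxidative phosphorylation list (-0.32, -0.67 to -0.02) were also lower in colon, and the cell cycle list was higher (0.37, 0.02 to 0.68). All colon cells belonged to the umi barcode set, and within that set the log2 ratio was -1.12 (-1.66 to -0.66) for the NF-kB list and -0.67 (-1.22 to -0.17) for the interferon list. There the non-lymphoid list (-0.18, -0.45 to 0.07) and the oxidative phosphorylation list (-0.12, -0.52 to 0.26) were not separable from 0, and the core list (-0.35, -0.72 to -0.01) and the immediate early and stress list (-0.27, -0.56 to -0.01) had intervals that ended just below 0. The cell cycle list had 0.59 (0.15 to 1.02) in that set.

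The genes named as lower in colon included the cytokine receptor Il7r, found in 0 of 16 colon cells (a share of up to 18.8%), 50% of VAT and 56.5% of muscle day 1 cells. Cd40lg, which signals to antigen-presenting cells, was found in 6.25% of colon, 63.6% of VAT and 76.5% of muscle day 1 cells. S1pr4, Cyba, Grap, Ube2d2a, Ptpn22, Ppp2r5c, Klhl6 and Mgea5 were found in no colon cell, and Zfp36l2 in 1. Higher in colon beside Il10 were the chaperone partner Bag3 (37.5% of colon cells) and Chchd10, a mitochondrial protein (56.2%), with Mir1934, Zdhhc6, Olfr582, Rbfox3, D10Jhu81e, Tmcc2 and Abca16. Hba-a1 and Hbb-bs, each in 43.8% of colon cells and in no VAT or muscle cell, belong to red cells. Foxp3 was found in 0 of 16 colon cells, 22.7% of VAT cells (interval 7.82 to 45.4), 8.24% of muscle day 1 cells (3.38 to 16.2) and 15.8% of muscle day 4 cells (3.38 to 39.6).

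Visceral fat regulatory T cells are known for the interleukin-33 receptor ST2, and the VAT comparison asked what set these cells apart from colon and muscle cells. Nearly all VAT cells had recorded CD25, ST2 and Klrg1 fluorescence well above 0, and the sort gates were not given. For Il2ra, Il1rl1 and Klrg1, selection of such cells by the sort could therefore not be told apart from tissue. Il1rl1, which encodes ST2, was found in 16 of 22 VAT cells (72.7%, interval 49.8 to 89.3), 6.25% of colon cells (0.158 to 30.2), 24.7% of muscle day 1 cells (16.0 to 35.3) and 42.1% of muscle day 4 cells (20.3 to 66.5). Few VAT cells had transcripts of the cytotoxic protease Gzmb, found in 1 of 22 VAT cells (4.55%, interval 0.115 to 22.8) but in 62.5% of colon, 69.4% of muscle day 1 and 89.5% of muscle day 4 cells. Gata3, a factor that drives ST2 expression, was found in 77.3% of VAT, 50% of colon and 41.2% of muscle day 1 cells.

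The VAT regulatory T cell list (18 genes) had a log2 ratio of 0.27 (-0.08 to 0.61), not separable from 0. Its members went both ways: Dgat1, an enzyme of fat storage, was found in 13.6% of VAT and 55.3% of muscle day 1 cells, while Pparg, the fat-cell regulator, was found in 9.09% of VAT cells and in 0 of 16 colon cells. The NF-kB and TNF receptor family list (0.53, 0.23 to 0.80), the interferon response list (0.39, 0.08 to 0.68) and the oxidative phosphorylation list (0.30, 0.04 to 0.56) were higher in VAT than in the mean of colon and muscle. For NF-kB and interferon genes this came from colon: per 1000 detections the lists made up 4.09 and 3.52 in VAT, 4.09 and 3.54 in muscle day 1, and 1.74 and 1.81 in colon cells. In the umi barcode set alone, with 9 VAT cells, the NF-kB (0.36), interferon (0.40) and oxidative phosphorylation (0.35) ratios had 0 inside their intervals. Anxa1, which encodes a mediator that restrains inflammation, was found in 13 of 22 VAT cells (59.1%, interval 36.4 to 79.3), in 0 of 16 colon cells and in 5.88% of muscle day 1 cells. Tnfsf11, which encodes RANKL, was found in 40.9% of VAT and 0 of 85 muscle day 1 cells, and the integrin Itga4 in 63.6% of VAT and 10.6% of muscle day 1 cells. AA467197, Lztfl1, Exoc1, Nae1, Unc119b, Cd200r1, Pcyt1a, Smu1 and Tnk2 were also higher in VAT. Cd200r1 had the opposite direction within the umi barcode set. Beside Gzmb, the genes lower in VAT were Ganab, Rbfox3, Phc1, Phlda1, Mblac2, Src, Ipo9, Cd59a, Dtd2, Nckap1l and Camk2b.

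Muscle cells of both days were compared with colon and VAT cells to find transcripts distinct to injured muscle. Ccr3, Icam1 and Stat4 were found in more muscle than colon or VAT cells, while the migration and adhesion list as a whole was not separable from 0 (0.11, -0.12 to 0.34). Members of that list also went the other way, such as Itga4 (10.6% of muscle day 1 and 63.6% of VAT cells) and Ccr9 (8.24% of muscle day 1 and 37.5% of colon cells). Ccr3, a receptor for eotaxins, was found in 38.8% of muscle day 1 cells (interval 28.4 to 50.0), 42.1% of muscle day 4 cells (20.3 to 66.5), 6.25% of colon cells and 0 of 22 VAT cells, which allows a share of up to 13.6%. The adhesion ligand Icam1 was found in 29.4% of muscle day 1, 52.6% of muscle day 4, 4.55% of VAT and 0 of 16 colon cells. Stat4, which relays interleukin-12 signals, was found in 30.6% of muscle day 1, 42.1% of muscle day 4 and 9.09% of VAT cells.

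The muscle regulatory T cell list (14 genes) had a log2 ratio of 0.48 (0.20 to 0.79), 0.37 after thinning, and its median lay at percentile 99.3 of matched random lists. Its member Itgae, the integrin CD103, was found in 51.8% of muscle day 1, 18.8% of colon and 9.09% of VAT cells. Il18r1, the interleukin-18 receptor, was found in 18.8% of muscle day 1 and 9.09% of VAT cells and in 0 of 16 colon cells, which was not separable at this depth. The growth factor Areg was found in 32.9% of muscle day 1 and 40.9% of VAT cells. The regulatory T cell core list (0.30, 0.09 to 0.50), the NF-kB and TNF receptor family list (0.44, 0.20 to 0.69), the interferon response list (0.41, 0.15 to 0.68), the immediate early and stress list (0.20, 0.04 to 0.35) and the non-lymphoid regulatory T cell list (0.17, 0.03 to 0.32) were higher in muscle than in the mean of colon and VAT, and the cell cycle list was lower (-0.36, -0.61 to -0.10). The NF-kB and interferon lists in muscle lay within the counting intervals of VAT, so their difference came from the low colon values. The immediate early and non-lymphoid lists were below their VAT values in muscle day 4 cells. In the umi barcode set alone, the day 4 part of the muscle mean rested on 2 cells. There the muscle list (0.57, 0.03 to 1.08) and the NF-kB list (0.55, 0.07 to 1.01) kept intervals above 0. The core (0.31), interferon (0.19), immediate early (0.03), non-lymphoid (0.18) and cell cycle (-0.19) lists had 0 inside theirs. Ctla4, an inhibitory receptor of regulatory cells, was found in 84 of 85 muscle day 1 and 19 of 19 muscle day 4 cells, against 59.1% of VAT and 87.5% of colon cells.

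Tmem140 had the largest size in muscle: it was found in 54.1% of muscle day 1 and 47.4% of muscle day 4 cells and in no colon or VAT cell. Spty2d1, Mrap2, Slc25a19, Matk, Igflr1, Pde4b, Rell1 and Klhl6 were also higher. The stress chaperone Hspa1b was found in 0 of 85 muscle day 1 cells, which allows up to 3.53%, and in 45.5% of VAT and 18.8% of colon cells. Serpinb6a, a protease inhibitor, and Hmgn2, a nucleosome-binding protein, were lower in muscle too, with Rnu2-10, Sbk1, Sfxn3, Rsbn1, Trim59, Ift80, Rcc2, Ppil4 and Arhgef3.

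**Figure D3:**
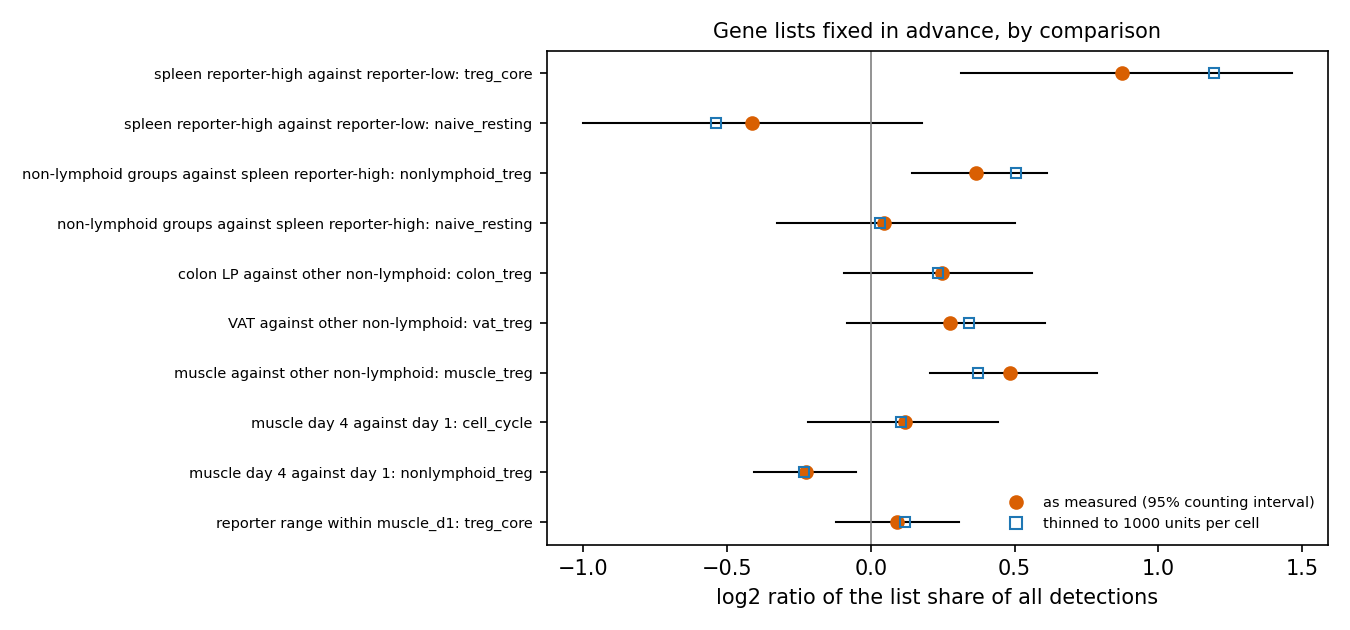
Log2 ratio of a gene list's share of all detections (x axis) for the lists and comparisons chosen in advance (y axis); circles are measured values, lines 95% counting intervals and squares values with each cell thinned to 1000 units. Intervals lay above 0 for the core list in spleen (0.87), the non-lymphoid list outside the spleen (0.36) and the muscle list in muscle (0.48), and below 0 for the non-lymphoid list at day 4 (-0.23).

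The comparison of day 4 with day 1 asked how muscle CD4 T cells differed with time after injury. Few transcripts separated the days, and the proliferation genes did not. Mt2, which encodes a metal-binding stress protein, was found in 9 of 19 day 4 cells (47.4%, interval 24.4 to 71.1) and 3 of 85 day 1 cells (3.53%, 0.734 to 9.97). Thinned to 1000 units, Mt2 stood at 17.5% and 1.71%, and in the umi barcode set, with 2 day 4 cells, its direction was the opposite. The cell cycle list had a log2 ratio of 0.12 (-0.22 to 0.44), and the proliferation marker Mki67 was found in 15.8% of day 4 and 10.6% of day 1 cells. The non-lymphoid regulatory T cell list made up 9.29 per 1000 detections at day 4 and 10.9 at day 1, a log2 ratio of -0.23 (-0.41 to -0.05). Its member Gzmb was found in 89.5% of day 4 and 69.4% of day 1 cells. Mrpl39, a mitochondrial ribosome protein (42.1% against 5.88%), and Mapkapk2, a stress-activated kinase (42.1% against 15.3%), were higher at day 4. The adhesion molecule L1cam (26.3% against 55.3%), Notch2, Kdm4a and Coq10b were lower at day 4. The regulatory T cell core list had a log2 ratio of -0.23 (-0.48 to 0.01), the helper effector list 0.14 (-0.47 to 0.72) and the MHC class I list -0.16 (-0.49 to 0.17). Day 4 rested on 1 library pool, so the day and the pool could not be told apart.

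Within muscle at day 1, cells with reporter fluorescence of at least 10000 (42 cells) were compared with the 43 below it, to ask whether regulatory genes followed the reporter. They did not separate the ranges. The dimmer range ran from 765 to 9909, and nearly all its cells lay above the reporter-low spleen cells (236 to 1375). The split could therefore hardly compare cells with and without the reporter, and only asked about brighter against dimmer cells. The regulatory T cell core list had a log2 ratio of 0.09 (-0.12 to 0.30), and 0.05, 0.05 and 0.21 within the 3 library pools, each with 0 inside its interval. Foxp3, split at the median fluorescence, was found in 2 of 43 brighter cells (4.65%, interval 0.568 to 15.8) and 5 of 42 dimmer cells (11.9%, 3.98 to 25.6). Gimap5, a GTPase needed for lymphocyte survival, Tmem181a and Wdr41 were each found in 9 of 42 brighter and 1 of 43 dimmer cells. Lax1, an adaptor that dampens antigen-receptor signals, was found in 4.76% of brighter and 27.9% of dimmer cells, and Kcmf1, Tmed9 and Cisd2 were also lower in brighter cells. The fluorescence had no gap at the limit, and 18 cells lay within 10% of it.

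Surface protein and transcript were compared within groups where the sort recorded both. In VAT, Il1rl1 was found in 10 of 11 cells with brighter ST2 (90.9%, interval 58.7 to 99.8) and 6 of 11 with dimmer ST2 (54.5%, 23.4 to 83.3). Klrg1, an inhibitory receptor, gave the same counts for its own protein. Il2ra was found in 81.8% of VAT cells with brighter CD25 and 63.6% of those with dimmer CD25, and in 1 of 21 brighter and 0 of 20 dimmer spleen cells. In colon, the recorded Nrp1 fluorescence lay around 0, so a split by it could not separate cells with and without the protein. Foxp3 was found in 1 of 10 brighter and 2 of 9 dimmer cells of muscle at day 4 and in no spleen or colon cell. In each pair the intervals overlapped.

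Transcripts of cells other than CD4 T cells gave the background of the sort. Cd79a, a B cell gene that T cells lack, was found in 9.52% of reporter-high spleen (median 899 genes), 25% of colon (median 1507.5 genes), 4.55% of VAT and 1.18% of muscle day 1 cells, and Cd8a, a marker of CD8 T cells, in 9.52%, 6.25%, 0 of 22 and 1.18%. Other members of the same lists were more frequent in VAT. Cd79b and Cd8b1 were each found in 18.2% of VAT cells, and in 6.25% and 12.5% of colon cells. Reporter-low spleen cells (median 888 genes) had larger shares of several such genes, with Cd79a in 30.8%, Cd19 in 23.1% and Hbb-bs in 76.9%. There the red cell list made up 2.63, the neutrophil list 1.52, the macrophage list 1.38 and the B cell list 1.04 per 1000 detections. In the order reporter-high spleen, colon, VAT and muscle day 1, the red cell list made up 1.46, 1.03, 0.0273 and 0.0162 per 1000 detections, and the neutrophil list 1.46, 0.592, 0.409 and 0.267. The macrophage, monocyte and dendritic cell list made up 1.33, 1.07, 0.736 and 0.736, the B cell list 0.532, 0.592, 0.436 and 0.121, and the CD8 T and NK cell list 0.266, 0.237, 0.218 and 0.259. The adipocyte list (0.191 in VAT), the muscle fibre list (0.0647 in muscle day 1) and the fibroblast list (0.473 in colon) stayed low, and the colon epithelium list had no detection in colon. The endothelial list made up 0.129 per 1000 detections in muscle day 1 and none in VAT.

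Positions of the leading genes on the GRCm38 build were as follows in the GENCODE annotation. Foxp3 lies on chromosome X from 7573644 to 7595245 and Il2ra on chromosome 2 from 11642807 to 11693193. Il1rl1 lies on chromosome 1 from 40429570 to 40465415, Il10 on chromosome 1 from 131019845 to 131024974 and Gzmb on chromosome 14 from 56258838 to 56262260. Tnfrsf18 lies on chromosome 4 from 156026164 to 156028895, Ifi27l2a on chromosome 12 from 103442167 to 103443680, Anxa1 on chromosome 19 from 20373428 to 20390944, Mt2 on chromosome 8 from 94172664 to 94173568 and Ccr3 on chromosome 9 from 124021972 to 124031689.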

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

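Among the tests of this part, those of a single library pool for the spleen pattern, of depth for the colon and non-lymphoid lists, and of enzyme digestion were chosen only after the results were seen.

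Data outside the comparisons held signal of 2 kinds. The 30 muscle day 4 cells left out for low depth held a summed level of 667 in total, all in 1 library pool, with a median of 15 per cell. The labels also give each cell of spleen, colon and muscle a count of the reporter transcript, which the deposited table lacks. It was above 0 in 6 of 21 reporter-high spleen cells (28.6%) and in 0 of 13 reporter-low cells, which allows a share of up to 23.1%. In colon it was above 0 in 3 of 16 cells (18.8%, interval 4.05 to 45.6). It was above 0 in 40 of 85 muscle day 1 cells (47.1%) and 13 of 19 muscle day 4 cells (68.4%). In muscle at day 1 it was found in 26 of 42 cells of the brighter reporter range and 14 of 43 of the dimmer range, where the Foxp3 transcript itself was found in 7 of 85 cells.

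Red cell transcripts were present in most spleen cells, with 1 or more in 61.9% of reporter-high and 84.6% of reporter-low cells against 4.55% of VAT cells. Neutrophil transcripts were found too, with S100a9 in 42.9% of reporter-high cells, but the tests below used red cell transcripts only. The sort required TCRb and CD4 on live cells. A single library pool is argued against for red cell transcripts, since the lowest share over the 3 spleen pools was 61.5%. RNA of red cells in the wells may be the source: Hba-a1 and Hbb-bs, each in 23 of 41 cells, were found together in 18 cells, 1.40 times the 12.9 that independent detection gives, which does not settle it. The most abundant red cell genes were also found in colon cells, with Hba-a1 in 43.8% of them. Cells with many reads per unit did not have more red cell transcripts: the share was 61.9% in the cells above the median of reads per unit and 80% below it, a difference of -18.1 points within the counting interval. Mechanical dissociation and age go with the spleen, but cannot by themselves account for the haemoglobin transcripts of colon cells, which were digested with enzymes. Library pools of spleen and colon had consecutive names. Their median mapped reads per unit were 78.1 and 120, against 26.9 in VAT, 23.9 in muscle day 1 and 44.2 in muscle day 4 cells. What these pools share as a set was not tested and stays open, as do strain and a difference between tissues.

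The NF-kB and TNF receptor family list was lower in colon than in VAT and muscle. The barcode set is argued against, since within the umi set the log2 ratio was -1.12 (-1.66 to -0.66). A single library pool is argued against too, since with each pool left out in turn the ratio stayed between -1.39 and -0.99. Depth is argued against by the thinned ratio of -1.25. Strain, age, the reporter, the library pools as a set and the tissue itself remain open as untested, since each goes with the group.

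The non-lymphoid regulatory T cell list was higher outside the spleen by a log2 ratio of 0.36. The thinned ratio, which leaves out cells under 1000 units, was 0.50 (0.21 to 0.84). The ratio among cells with 1000 to 2000 genes was 0.20 with 0 inside its interval, so depth stays open. Within the umi set the ratio was 0.047, with an interval from -0.23 to 0.34, so the barcode set cannot be told apart from depth in 10 spleen cells. Enzyme digestion, which induces stress genes, may contribute: the immediate early and stress list was higher outside the spleen by 0.25. In the umi set that list made up 7.51 per 1000 detections in reporter-high spleen cells. It made up 6.94 in colon, 8.76 in VAT, 8.55 in muscle day 1 and 7.51 in muscle day 4 cells there. Colon, also digested, was thus not higher. Digestion and tissue cannot be told apart because only spleen was dissociated mechanically. A biological difference between tissues stays open as well.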

How the results depend on the processing

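The alternatives that sum the levels as deposited that keep cells with 1000 to 2000 genes, and that compare the reporter ranges within each library pool were chosen after seeing the data; the others were fixed before. No paired analysis was possible by replicate number, because the replicate numbers in the labels only number single cells. Library pools held both reporter ranges in spleen and in muscle at day 1, and there the ranges were compared within each pool. A count-scaling alternative was not run because the values are not counts.

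For the 10 list results chosen in advance, 151 of 157 alternative values stayed within the counting interval and 6 moved outside it. None reversed a called direction, but only results whose interval excluded 0 could be so labelled. Of the others, the naive and resting list kept its sign in 14 of 16 alternatives in spleen and 16 of 20 outside it. The cell cycle list at day 4 kept it in 10 of 11, and the core list in the muscle reporter ranges in 14 of 15. The alternatives reused the same cells or parts of them. The core list in spleen kept its direction in all 16 alternatives (0.56 to 1.43), the muscle list in all 16 (0.37 to 0.57) and the colon list in all 16 (0.20 to 0.35). The naive and resting list in spleen was -1.15 in the ls set only and 0.02 in the umi set, so the difference rested on the ls cells. Within the library pools it was -1.18, 0.13 and -0.17, and the cause of this spread was not tested. The non-lymphoid list outside the spleen was 0.68 with each cell weighing the same, 0.66 against all spleen cells and 0.047 in the umi set only. The first gives shallow cells more weight by construction; the cause of the others was not tested. The cell cycle list at day 4 was -0.25 in the umi set only, with 2 day 4 cells. Of the other list values, 1612 of 1643 stayed within their intervals.

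Of the genes named, the number also named with a pseudocount of 300 was 5 for the non-lymphoid groups, 2 for VAT, 1 for muscle, 0 for day 4 against day 1 and 0 for the muscle reporter ranges. With a pseudocount of 10 it was 13 for VAT and 10 for muscle. A larger pseudocount lowers every size, so fewer genes reach the minimum. One by one, 265 of 306 alternative values of named genes stayed within their intervals, 39 moved and 2 reversed. Both reversals were in the umi set: Cd200r1 in VAT by -7.07 points of percent and Mt2 at day 4 by -13.6 points, and the cause was not tested. With 19 day 4, 16 colon and 13 reporter-low cells, a count of 0 cannot exclude shares up to 15.8%, 18.8% and 23.1%, taken as 3 cells.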

Other observations

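These values were looked up after the comparisons were seen. Several transcripts were found in a larger share of spleen and colon cells than of VAT and muscle cells. Chchd10 was found in 21 of 57 spleen and colon cells and 3 of 126 VAT and muscle cells, D10Jhu81e in 21 and 2, Hbb-bs in 30 and 0, S100a9 in 19 and 1, and Marcksl1 in 31 and 18. Il10 was found in 37 of 57 and 30 of 126 cells, and in 46.2% of reporter-low spleen cells. Ifi27l2a had the opposite order, in 6 of 57 and 105 of 126 cells. For Il10 and Ifi27l2a the difference of colon from VAT and muscle was thus shared at least in part by spleen. Whether it follows tissue or library pools was not tested.

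Genes known from other tissues were detected in most of the 183 cells: Chrm4, a muscarinic receptor, in 99.5%, Prdm16 in 88.5%, Col4a3 in 86.9%, Gja5 in 82.5% and Cyp1a2 in 82.0%. Each of the 1123 olfactory receptor genes was found in 0.356% of cells on average, with 3.99 such genes per cell. A gene of the whole table was found in 6.08% of cells on average.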
